A study of Homo sapiens with 8 samples.

How the data were processed

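RNA was sequenced from SCC13 cells infected at a multiplicity of infection of 50 with Adeno-GFP or Adeno-DLX3 and collected at 18, 24, 36 and 48 h. Per the labels' protocols, the cells were moved from 10% to 1% serum at infection, and libraries were read on an Illumina HiSeq 2500. The extraction label speaks of skin, whereas the cell line, source and growth labels name SCC13; the latter were followed. Per the file headers, reads were mapped to the human genome hg19 with TopHat, and the authors calculated RPKM per RefSeq transcript in Partek. The submitters' processing notes name TopHat2 2.0.8, Bowtie2 and Partek 6.6. Read filters and which reads RPKM was divided by are not given in the sources used here. The deposited table held RPKM values for 52085 transcripts of 25855 gene symbols in 8 columns, and each column was matched to its sample by virus and hour. The annotation at hand follows another build (GRCh38), so no coordinates are given, and it was used only for transcript length, GC content and current names.

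RPKM values are not counts, so depth was estimated from the size of the step that 1 read makes in olfactory receptor, taste receptor, trace amine receptor and keratin-associated protein genes, and from the commonest ratio between libraries over low genes. This gave 53.7, 38.6, 50.6 and 37.3 M reads for Adeno-GFP at 18, 24, 36 and 48 h, and 62.8, 34.6, 50.1 and 52.8 M for Adeno-DLX3. A floor of 3 reads over 1 kb then corresponds to 0.0478 to 0.0866 RPKM. The largest gap in depth set the 3 libraries of 38.6 M reads or less apart from the other 5.

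Values were summed per gene symbol, scaled by median of ratios (factors from 0.946 to 1.05) and put on the scale of log2(RPKM + 0.5). Genes with RPKM of 1 or more in at least 4 of the 8 libraries were kept, 11860 of 25855. Tests used limma 3.58.1 in R 4.3.3 with trended empirical Bayes moderation and Benjamini-Hochberg adjustment at 0.05, two-sided. The DLX3 comparison fitted hours as a factor plus virus, with 3 residual degrees of freedom and a prior of 4.52. The change of the effect added virus by centred hours (2 residual degrees of freedom), and the hours comparison fitted virus plus linear hours (5), without a term for the pairing. The 4 hours pair the libraries by design. Among libraries of the other arm, each correlated best with that of its own hour, in deviations from arm means (r from 0.634 to 0.741). Slopes were multiplied by 30 h to give the change from 18 h to 48 h.

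The comparisons, 37 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as later. The 34 lists with 5 or more tested members went into camera with a correlation of 0.01, camera with an estimated correlation, and fry. With an estimated correlation camera rests on the residual degrees of freedom of the fit (3, 2 and 5). It therefore has little power here to pass a list after adjustment. Named genes were DLX3, the 8 largest rises and 8 largest falls among genes that passed with 1 sign at all 4 hours and a mean RPKM of 1 or more in an arm, up to 4 passing members per list by p (or 2 not passing where none did), a panel of 13 genes, and 5 rises and 5 falls for each hours comparison; 2 genes picked by this rule, 1 of them among the 8 falls, were left out of the named genes without replacement, which leaves 7 falls, and the text does not name every other gene picked; the lists over hours are illustrated with genes so named. A list's median at a single hour was also set beside 10000 random lists matched on mean expression in 20 bins, but these carry no spread between libraries, so those percentiles are not given.

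The scripts were tested on simulated data for the 11860 genes, with 100 genes changed at each of 2 sizes. In the DLX3 comparison, 100% of genes changed by log2 1 or 2 were recovered, with 9 false calls among 209 (4.31%). For the change of the effect, 98% were recovered at 0.05 and 100% at 0.1 log2 per hour, with 26 false calls among 224 (11.6%), more than the nominal rate. For hours, 81% were recovered at 0.03 and 100% at 0.06, with 7 false calls among 188 (3.72%). With no gene changed, 1, 3 and 0 genes were called. A list of 38 genes shifted by 0.5 was found, with 0 of the other lists called. Noise was drawn independently for each gene and library. The simulations thus lack the correlation between genes of a list, estimated in the data at 0.550 for interferon genes. For hours they also lack the shared deviation of the 2 libraries of an hour. False calls among lists and over hours can therefore exceed those simulated.

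Alternatives were leaving out each pair, no further scaling, quantile normalization, pseudocounts of 0.1 and 1, no filter, a filter of RPKM 5, the transcript with the highest mean in place of gene sums, robust moderation, no block for hours, a threshold of 0.1 and hours as ranks. A depth term, the 18 h and 36 h pairs alone, hours on the mean of each pair, and the removal of very short RNA genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.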

Results

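RNA sequencing was carried out on SCC13, an established human cell line from a cutaneous squamous cell carcinoma, after infection with an adenovirus carrying the homeobox transcription factor DLX3 (Adeno-DLX3) or a green fluorescent protein control (Adeno-GFP). DLX3 takes part in the terminal differentiation of the epidermis. Cells of each arm were collected at 18, 24, 36 and 48 hours after infection, with 1 library per virus and hour, which gave 4 libraries per arm and 8 in all. The 4 libraries of an arm are therefore times and not replicates. The estimated depth ran from 34.6 M reads in the Adeno-DLX3 24 h library to 62.8 M in the Adeno-DLX3 18 h library. Values were RPKM per transcript, summed per gene, and 11860 genes were tested. Each fold change below is on the scale of log2(RPKM + 0.5), which understates the change of low genes, and rests on 4 time-matched pairs. No virus and hour has a replicate, so the p-values for DLX3 measure only the spread between the pairs.

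The hour after infection separated the libraries first. Among libraries of the other arm, each library was closest to that of its own hour. Correlations of the deviations from the arm means were 0.741, 0.696, 0.668 and 0.634 across genes at 18, 24, 36 and 48 h. With the arm means kept, the 18 h libraries correlated most with each other (0.992). At 36 h and 48 h, however, each library correlated more with a library of its own arm than with its partner. The 36 h and 48 h Adeno-DLX3 libraries correlated most with each other (0.987), against 0.984 and 0.971 with their partners. The 36 h Adeno-GFP library was closest to the 18 h one of its arm (0.986 against 0.984). The 48 h Adeno-GFP library was closest to the 36 h one (0.972 against 0.971). The 24 h libraries of both arms and the 48 h Adeno-GFP library had the lowest estimated depths, of 38.6, 34.6 and 37.3 M reads, against 50.1 to 62.8 M in the other 5. The same 3 libraries had the lowest values on the second principal component. The 48 h pair was thus split between these depth classes, while the other pairs were not.

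**Figure D1:**
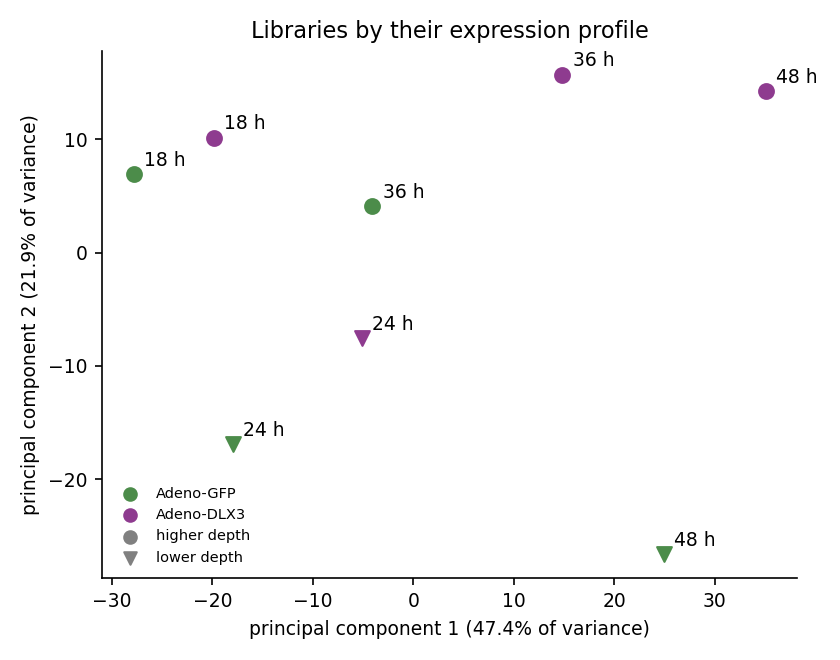
Each point is 1 library, placed by the first principal component (47.4% of the variance, horizontal axis) and the second (21.9%, vertical axis) of the log2 expression values; colour gives the virus, shape the depth class, and the number the hours after infection. The 3 libraries of lower depth lie below 0 on the second component and the other 5 lie above 0.

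The first comparison asked which genes differed between Adeno-DLX3 and Adeno-GFP over the 4 hours. A change or effect of DLX3 below means this difference. The design cannot tell DLX3 itself from other differences between the viruses, such as vector, dose or the GFP cargo. DLX3 itself had 2.98, 3.65, 5.51 and 4.65 RPKM in the Adeno-GFP libraries at 18, 24, 36 and 48 h, and 165.0, 191, 305 and 444 RPKM in the matching Adeno-DLX3 libraries. Its log2 fold change was 5.81 (SE 0.15, limma adjusted p = 6.29e-06). The interstitial collagenase MMP1 rose from a mean of 0.514 to 33.2 RPKM (log2 fold change 5.05, SE 0.19). The hair keratin-associated protein gene KRTAP3-1 rose from 0.0537 to 7.52 RPKM (3.76, SE 0.17). PAPSS2, which makes the sulfate donor PAPS, rose by 2.99 (SE 0.22), the basement membrane component NID1 by 2.41 (SE 0.31), the G protein regulator RGS2 by 2.40 (SE 0.18), TOX by 2.12 (SE 0.18) and the thrombin receptor F2R by 1.92 (SE 0.21). Adjusted p for these 7 genes lay between 4.18e-05 and 0.0112.

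The strongest falls held both cytokines and secreted regulators. The neutrophil chemokine CXCL8 fell from 23.0 to 9.06 RPKM (log2 fold change -1.32, SE 0.14, adjusted p = 0.00585). The interleukin 1 alpha gene IL1A had -1.19 (SE 0.14) and the gap junction gene GJA5 -1.28 (SE 0.16). Tissue plasminogen activator (PLAT, -1.16, SE 0.24) and the Wnt antagonist SFRP1 (-1.12, SE 0.20) also fell. The first ranks went to beta globin (HBB) and growth hormone (GH1), genes that epithelial cells do not normally use. HBB had a mean of 21.5 RPKM in the Adeno-GFP libraries and 0.0346 in the Adeno-DLX3 libraries, or about 2464 estimated reads against 3, a ratio of 913 after scaling to the summed estimated depth of each arm (95% counting interval 312 to 4430.4). GH1 had means of 14.6 and 0.0124 RPKM, about 1910 reads against 2, a ratio of 1062 after the same scaling (293 to 8772). These Clopper-Pearson intervals cover counting error only.

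**Figure D2:**
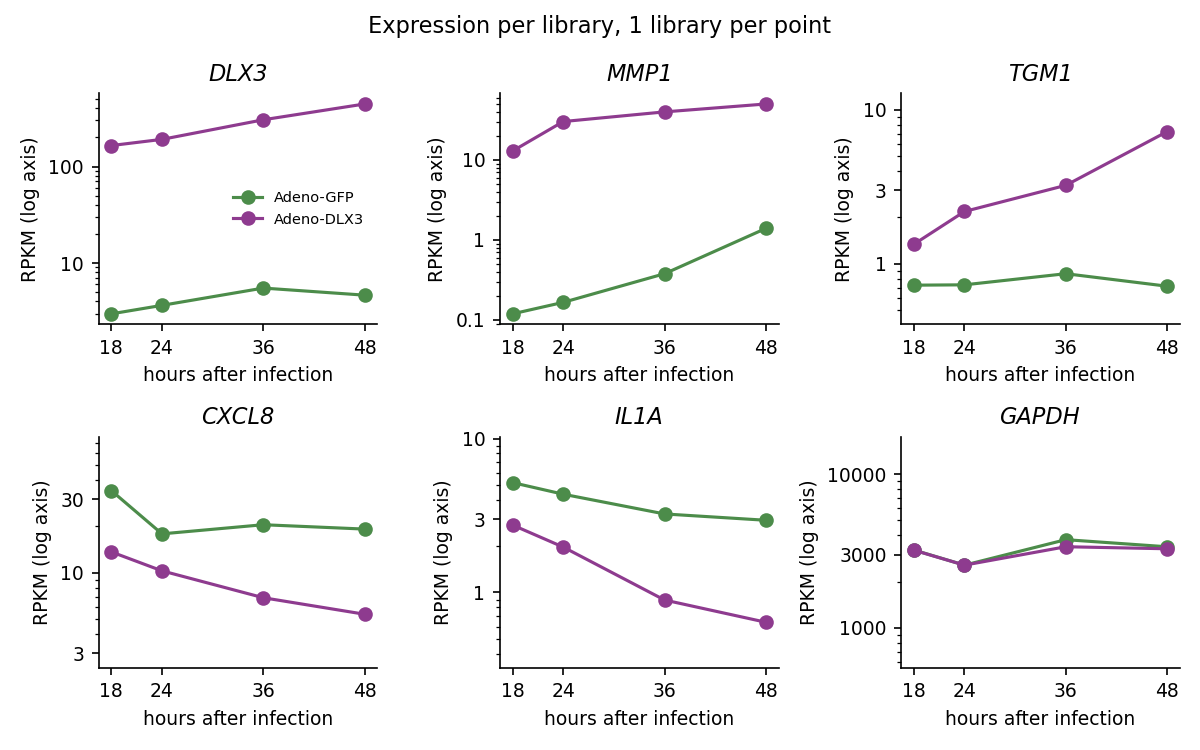
RPKM (vertical, log axis) against hours after infection (horizontal) for 6 genes, with 1 library per point, Adeno-GFP in green and Adeno-DLX3 in purple. DLX3, MMP1 and TGM1 were higher and CXCL8 and IL1A lower in the Adeno-DLX3 library at each of the 4 hours, while GAPDH did not pass the test (log2 fold change -0.04, SE 0.07).

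In all, 412 of 11860 genes passed (limma, Benjamini-Hochberg adjusted p under 0.05), 281 higher and 131 lower with DLX3. All 412 had the same sign at each of the 4 hours. The test sets the mean difference against the spread of these same 4 differences, so this adds no support. Their median absolute log2 fold change was 0.61, and 59 of those that rose and 13 of those that fell changed at least 2-fold. The count was 416 without the 18 h pair, but 57 without the 24 h pair, 42 without the 36 h pair and 810 (448 higher, 362 lower) without the 48 h pair, which is the set of pairs each within 1 depth class. Of the 58 genes picked for naming that passed, only DLX3, MMP1, KRTAP3-1, PAPSS2, RGS2, TOX, HBB, GH1, DST and PTGS2 passed in all 4 of them.

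**Figure D3:**
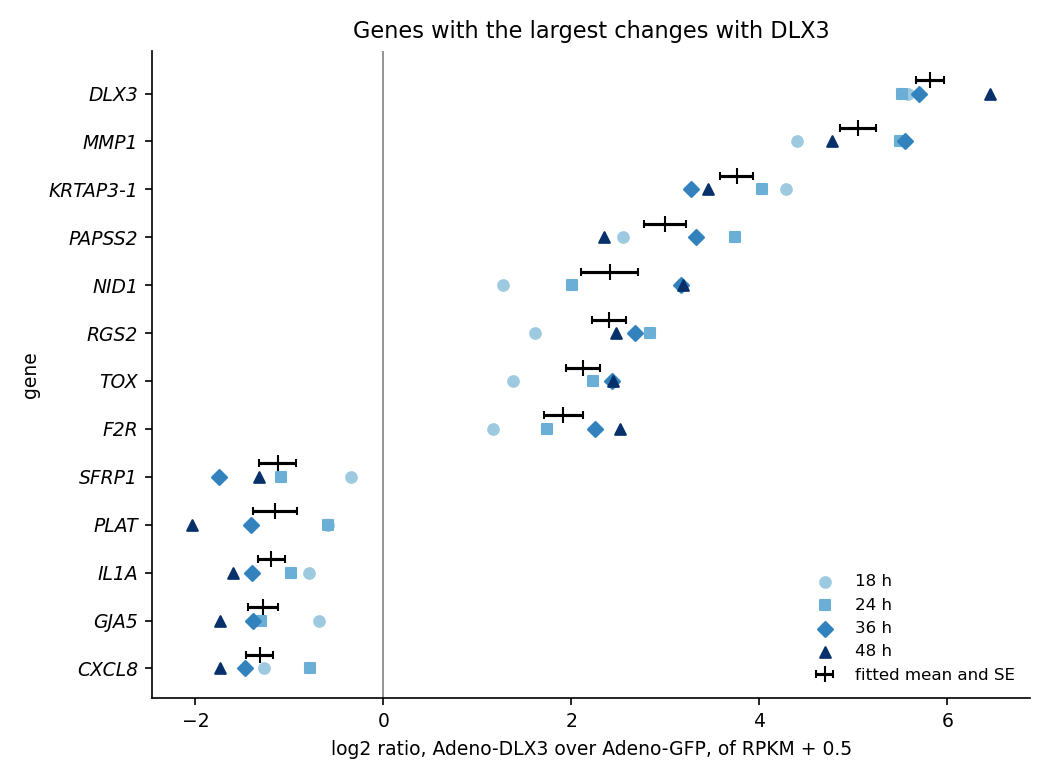
Log2 ratio of Adeno-DLX3 over Adeno-GFP (horizontal) at each hour for 13 of the genes with the largest rises or falls, HBB and GH1 not shown; black bars give the fitted mean and its SE. All points of a gene lie on the same side of 0, from 6.45 for DLX3 at 48 h to -2.03 for PLAT at 48 h.

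Keratinocyte differentiation genes did not move as 1 group. Of the 15 measured members of the terminal differentiation list, 2 rose and 1 fell (5 and 4 adjusted over the list alone). The crosslinking enzyme TGM1 rose (log2 fold change 1.47, SE 0.30), as did the transcription factor KLF4 (0.95, SE 0.12), while the calcium-binding CALML5 fell (-0.51, SE 0.09). KRT10 (-0.04, SE 0.08, adjusted p = 0.824) and IVL (-0.42, SE 0.11, adjusted p = 0.0885) did not pass, and KRT1 was under the expression filter. The list median was -0.02 and its mean 0.14. Simple and wound keratins were lower as a list (camera adjusted p = 0.0105, or adjusted p = 0.945 with an estimated correlation), with 2 of 7 members fallen, KRT16 (-0.76, SE 0.13) and KRT18 (-0.41, SE 0.09), and 5 adjusted over the list alone; with no filter this list had a camera adjusted p of 0.0727. None of these 5 named genes that changed (TGM1, KLF4, CALML5, KRT16 and KRT18) passed without the 24 h pair or without the 36 h pair.

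Adhesion is a theme of the study's title, and more genes rose than fell in each of the 3 lists that follow. The basal keratinocyte and cell-matrix lists share members that rose, ITGA2 and COL17A1 among them, so they are not separate support. Of 18 basal keratinocyte genes 4 rose and 1 fell (7 and 3 adjusted over the list alone): the hemidesmosome linker DST (log2 fold change 1.04, SE 0.11), the integrin subunit ITGA2 (0.77, SE 0.09) and collagen XVII (COL17A1, 0.50, SE 0.07) rose, and caveolin 1 (CAV1, -0.65, SE 0.10) fell. This list did not pass as a set (camera adjusted p = 0.519), and its median of -0.03 and mean of 0.07 differ in sign. Of 33 cell-matrix adhesion genes 5 rose and 0 fell (12 and 0 adjusted over the list alone), among them the integrin activator FERMT2 (0.81, SE 0.12) and ITGA6 (0.52, SE 0.08). Of 26 desmosome and cell-cell adhesion genes 2 rose, desmocollin 2 (DSC2, 0.75, SE 0.09) and desmoplakin (DSP, 0.41, SE 0.08), 0 fell (4 and 0 adjusted over the list alone) and 20 had an estimate above 0. Both adhesion lists passed camera (adjusted p = 0.0120 for cell-matrix and 0.00287 for cell-cell adhesion) but not with an estimated correlation (adjusted p = 0.945 for each), and cell-matrix adhesion had an adjusted p of 0.122 without the 48 h pair and a median of -0.02 at 24 h. Without the 24 h or the 36 h pair DST still passed, DSC2 passed only in the fit without the 24 h pair, and the other genes named here passed in neither.

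Cell cycle and cell death genes, the other themes of the title, had few members that passed for DLX3. Of the 38 G1/S and replication genes and the 37 G2/M and mitosis genes, 0 passed, over all genes or adjusted over the list alone, and the list medians were 0.00 and 0.00. At single hours, with 1 library against 1 and no test, G1/S genes had a median log2 ratio of -0.15 at 36 h and 0.17 at 48 h, and G2/M genes 0.10 at 48 h. The closest were the cyclin CCNE2 (0.25, SE 0.07, adjusted p = 0.0803) and the spindle protein NUSAP1 (0.31, SE 0.07, adjusted p = 0.0685), followed by RFC4 (-0.23, SE 0.07) and CDC25C (-0.27, SE 0.08). MKI67 had 0.06 (SE 0.09), the p21 gene CDKN1A 0.07 (SE 0.14), TP63 -0.17 (SE 0.12) and the cyclin D1 gene CCND1 -0.15 (SE 0.06), none of them passing. The signs of MKI67 without the 18 h pair and of CDKN1A without the 24 h pair were the opposite. Among 19 cell cycle arrest genes the stress gene GADD45B fell (-0.57, SE 0.10), 1 of 19 or 2 adjusted over the list alone, with a list median of 0.05 and mean of -0.05.

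Of 26 pro-apoptotic genes 2 rose and 0 fell (3 and 0 adjusted over the list alone), the BH3-only gene PMAIP1 (log2 fold change 0.40, SE 0.08) and the death-associated kinase DAPK1 (0.71, SE 0.10). Of 22 anti-apoptotic genes 1 fell (1 risen and 1 fallen adjusted over the list alone), the adaptor TRAF1 (-0.65, SE 0.10), and BCL2L1 did not pass (-0.05, SE 0.06). Camera passed neither list nor the cell cycle lists (adjusted p from 0.759 to 0.918). The pro-apoptotic list had a median of -0.01 and a mean of 0.05, the anti-apoptotic list -0.05 and 0.02. GADD45B, PMAIP1, DAPK1 and TRAF1 did not pass without the 24 h pair or without the 36 h pair.

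Inflammatory genes were mostly below 0 and interferon genes mostly above 0 in the fit, with both lists below 0 at 18 h. Of 19 inflammatory cytokine and NF-kB target genes 4 fell and 1 rose (9 and 2 adjusted over the list alone), with a list median of -0.30. CXCL8, IL1A and the chemokine CXCL2 (log2 fold change -1.05, SE 0.12) fell, while the prostaglandin synthase PTGS2 rose (1.43, SE 0.12). Of 38 interferon response genes 4 rose and 0 fell (5 and 2 adjusted over the list alone), and 32 had an estimate above 0. These were OASL (0.75, SE 0.10), HERC5 (0.73, SE 0.13), the RNA sensor DDX58 (0.63, SE 0.13) and SAMD9 (0.42, SE 0.07). Camera passed both lists, each with an adjusted p of 0.000826, against adjusted p = 0.945 with an estimated correlation. All 6 measured alarmin and antimicrobial genes had estimates below 0 and 0 of 6 passed (3 fell adjusted over the list alone). S100A9 had -0.97 (SE 0.30, adjusted p = 0.127) and S100A2 -0.44 (SE 0.11, adjusted p = 0.0760); camera gave an adjusted p of 0.0120 for the list, and adjusted p = 0.945 with an estimated correlation. Without the 36 h pair PTGS2 still passed and the other genes named here did not, and without the 24 h pair CXCL8, IL1A, CXCL2 and PTGS2 passed.

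Most genes of the ribosome and of its assembly had estimates slightly below 0, few of which passed. Of 42 ribosomal protein genes 41 had an estimate below 0, with a median of -0.13, and 1 fell, RPL13A (-0.28, SE 0.06), or 0 adjusted over the list alone. The median log2 ratio of these 42 genes was -0.17 at 18 h, -0.0029 at 24 h, -0.21 at 36 h and -0.16 at 48 h. Of 28 ribosome biogenesis and MYC target genes 25 were below 0 and the nucleolar GNL3 fell (-0.36, SE 0.06), 1 over all genes and 2 adjusted over the list alone. Of 21 hypoxia and glycolysis genes the hexokinase HK2 fell (-0.38, SE 0.08), 1 over all genes and 1 adjusted over the list alone. The camera adjusted p values were 5.32e-06, 0.000188 and 0.00180 for the 3 lists, against adjusted p = 0.945 with an estimated correlation for each, and the hypoxia list had 0.0778 without the 48 h pair. RPL13A, GNL3 and HK2 passed neither without the 24 h pair nor without the 36 h pair.

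Several signalling regulators changed while their lists did not pass camera, which looks for a shift in 1 direction. The homeobox gene MSX2 (log2 fold change 1.54, SE 0.23), BMP2 (0.71, SE 0.10) and the receptor TGFBR2 (0.42, SE 0.07) rose within the 19 BMP and TGF-beta genes, of which 3 rose and 1 fell (8 and 6 adjusted over the list alone). Of 16 Wnt genes 1 rose and 2 fell (3 and 2 adjusted over the list alone): the antagonist DKK1 rose (0.58, SE 0.11), and the receptor FZD7 (-0.70, SE 0.11) and SFRP1 fell. The EGFR feedback inhibitor ERRFI1 (1.01, SE 0.15) and the ligand EREG (0.37, SE 0.07) rose, 2 of 12 EGFR ligands and receptors (2 rose and 1 fell adjusted over the list alone). EGFR (-0.19, SE 0.13) and ERBB2 (0.09, SE 0.07) did not pass. The Notch target HES1 fell (-0.56, SE 0.08), 1 of 12 Notch genes (1 rose and 2 fell adjusted over the list alone), and the transcription factor SNAI2 fell (-0.67, SE 0.10), with MMP1 the other changed member among 17 epithelial-mesenchymal transition genes (2 rose and 4 fell adjusted over the list alone). Of 7 DLX family and partner genes DLX3 and MSX2 rose (2 rose and 2 fell adjusted over the list alone), with a list median of -0.10 and a mean of 0.91. DLX3 is the gene that the virus carries, so its rise was set by the design. Its log2 fold change of 5.81 is part of that mean. MMP1 and DLX3 were the only genes of this paragraph that passed in all 4 fits without a pair.

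Stress, lipid and control lists held few genes that passed. The phosphatase DUSP5 fell among 21 immediate early genes (log2 fold change -0.51, SE 0.08; 0 rose and 2 fell adjusted over the list alone, with a median of 0.06 and a mean of -0.02). The unfolded protein kinase EIF2AK3 rose (0.69, SE 0.11; 1 of 23, or 2 rose and 2 fell adjusted over the list alone), as did the cystine transporter SLC7A11 (0.48, SE 0.09; 1 of 21 NRF2 genes, or 2, with a median of -0.01 and a mean of 0.05), the sterol reductase TM7SF2 (0.59, SE 0.11; 1 of 24 cholesterol genes, or 1) and the ceramide enzyme DEGS1 (0.40, SE 0.07; 1 of 22 lipid genes, or 2 adjusted over the list alone). Over all genes and adjusted over the list alone, 0 of 13 heat shock, 0 of 16 histone, 0 of 26 oxidative phosphorylation, 0 of 7 humanin-like and non-polyadenylated RNA and 0 of 14 housekeeping genes passed, GAPDH and ACTB (0.16, SE 0.11) among the last. The adenovirus receptor CXADR rose (0.84, SE 0.10), 1 of 9 virus entry genes (2 adjusted over the list alone). Markers of other cell types were few: 2 of 12 fibroblast, 4 of 13 immune and 2 of 12 endothelial and melanocyte genes were measured, and only the lysosomal CD68 rose (0.41, SE 0.07). None of the genes that changed in this paragraph passed without the 24 h or the 36 h pair.

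Camera with a preset correlation of 0.01 passed 9 of 34 lists for DLX3, 3 higher and 6 lower. With an estimated correlation 0 lists passed (1 had an unadjusted p under 0.05). That version rests on 3 residual degrees of freedom and could hardly pass a list. For cell-cell adhesion the estimated correlation was 0.0126, near the preset 0.01, yet the unadjusted camera p went from 0.000507 to 0.0428. A call lost there is thus not shown to come from correlated genes. Larger estimates, 0.550 for interferon and 0.481 for ribosomal protein genes, leave that open. Over the alternatives the list median ranged from 0.08 to 0.24 for interferon, -0.53 to -0.12 for alarmin and -0.20 to -0.06 for ribosomal protein genes. The rotation test fry, which asks whether a list's genes move on balance in 1 direction, passed 0 (smallest adjusted p 0.0602). Its version without regard to direction passed 21 of 34 lists for DLX3, among them the Wnt, Notch, EGFR, and BMP and TGF-beta lists. That version passed 3 lists for the change of the effect and 29 for hours. A few changed members can be enough for it.

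**Figure D4:**
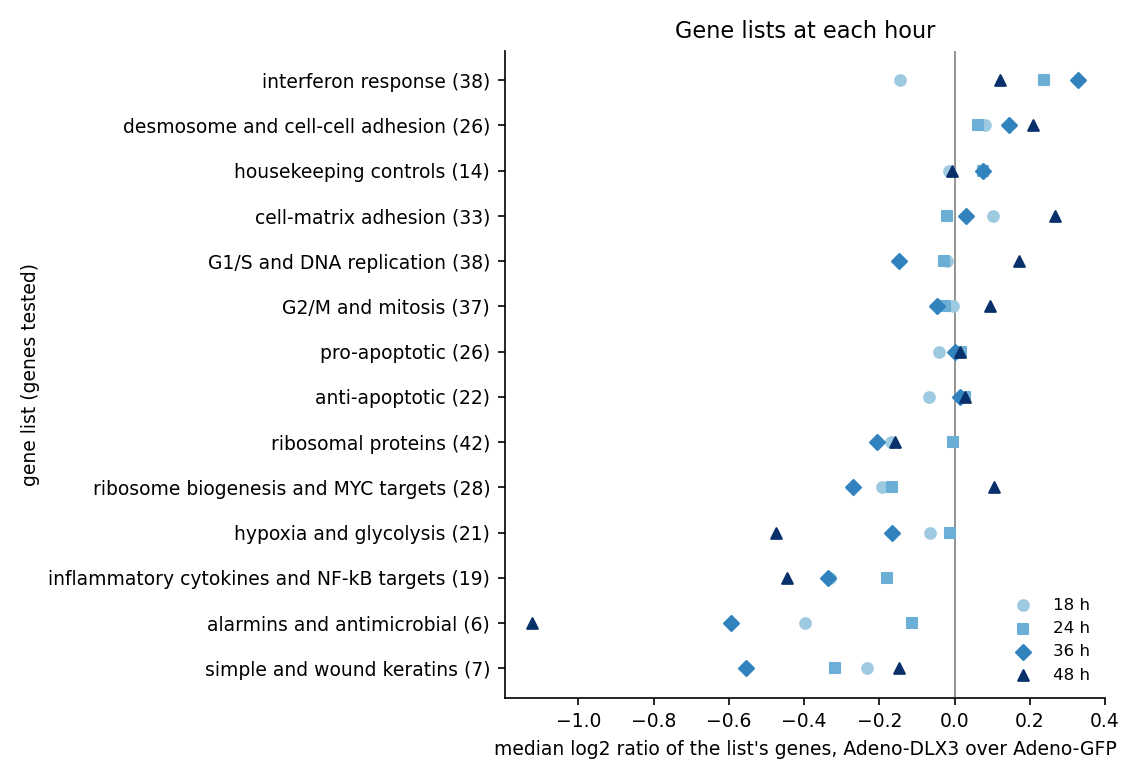
Median log2 ratio of Adeno-DLX3 over Adeno-GFP (horizontal) for the genes of 14 lists (vertical, with the number of genes tested) at each hour, including the 9 lists that passed camera. Inflammatory genes lay between -0.44 and -0.18 at all 4 hours, while interferon genes had -0.14 at 18 h, 0.33 at 36 h and 0.12 at 48 h.

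The difference at each single hour was described without a test, since 1 library was set against 1. At 18 h, 34 genes were at least 2-fold higher and 12 at least 2-fold lower with DLX3. These numbers were 78 and 28 at 24 h, 121 and 41 at 36 h, and 208 and 136 at 48 h. Across genes, which are not independent replicates, the ratios of 24 h and 36 h correlated most (Pearson r = 0.684) and those of 18 h and 48 h least (0.329). Interferon genes had a median log2 ratio of -0.14, 0.24, 0.33 and 0.12 at 18, 24, 36 and 48 h. Hypoxia genes went from -0.07 at 18 h to -0.48 at 48 h, and ribosome biogenesis genes from -0.19 at 18 h to 0.11 at 48 h.

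A further test asked for which genes the DLX3 effect itself changed with hours. The log2 effect on SERPINB2 grew by 2.69 (SE 0.34, adjusted p = 0.00828) from 18 h to 48 h, that on SERPINB7 by 2.41 (SE 0.24) and that on SERPINI1 by 2.20 (SE 0.29). Acetylcholinesterase (ACHE) gained 2.37 (SE 0.29) and the read-through gene DNAJC25-GNG10, which shares exons with its neighbours, 2.57 (SE 0.52). The effect dropped for the short RNA gene RNU86 (-2.87, SE 0.51), the endothelial cadherin CDH5 (-2.33, SE 0.30), the hypoxia gene NDRG1 (-2.11, SE 0.41), S100A8 (-2.11, SE 0.44) and ZBED6CL (-2.08, SE 0.32). Among genes named above, the effect grew for TGM1 (1.98, SE 0.27), NID1 (1.95, SE 0.34), MSX2 (1.49, SE 0.26), F2R (1.29, SE 0.26) and ERRFI1 (1.00, SE 0.17), and deepened for PLAT (-1.55, SE 0.23) and S100A9 (-1.99, SE 0.28). The slopes of these genes were not followed over the alternatives. S100A9 had log2 ratios of -0.34, -0.33 and -0.86 at 18, 24 and 36 h and -2.33 at 48 h. Its Adeno-GFP library had 101.9 RPKM at 48 h, against 27.6 to 37.0 before. NID1, in contrast, had ratios of 3.16 at 36 h and 3.18 at 48 h.

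In this test 229 genes passed, 124 with a rising and 105 with a falling effect. Immediate early and AP-1 genes leaned toward a rising effect (camera adjusted p = 7.6e-06, median change 0.52; 2 of 21 rose, 10 adjusted over the list alone), with median log2 ratios of -0.04, -0.03 and -0.13 at 18, 24 and 36 h and 0.49 at 48 h, so that the 48 h pair alone lay above 0. Interferon response genes did too (0.00252; 3 of 38, 8 adjusted over the list alone), as did EGFR ligands and receptors (0.0335; 2 of 12, 3 adjusted over the list alone). Hypoxia genes leaned the other way (0.000102; 2 of 21 fell, 6 adjusted over the list alone), with cholesterol biosynthesis (0.000241; 1 of 24, 1 adjusted over the list alone), alarmins (0.00831; 2 of 6, 3 adjusted over the list alone) and lipid synthesis genes (0.0385; 1 of 22, with 1 risen and 4 fallen adjusted over the list alone). With an estimated correlation 0 of 34 lists passed (smallest adjusted p = 0.851 with an estimated correlation, 0 with an unadjusted p under 0.05), and fry passed 0. Without the 48 h pair, which leaves only pairs within 1 depth class, 58 genes passed, 30 of them shared with the 229, and CDH5, DNAJC25-GNG10, ACHE, RNU86, NDRG1, S100A8 and ZBED6CL were not among them. Without that pair the slope of ACHE kept its size (0.0743 log2 per hour, against 0.0791 with it), while those of DNAJC25-GNG10 (0.0186 against 0.0855), NDRG1 (-0.0157 against -0.0703), S100A8 (-0.0154 against -0.0702), RNU86 (-0.0347 against -0.0957), ZBED6CL (-0.0313 against -0.0694) and CDH5 (-0.0480 against -0.0777) shrank. DNAJC25-GNG10 followed the depth class, with 0.0262 to 0.0417 RPKM in the 3 libraries of lower depth and 1.42 to 2.33 in the other 5. SERPINB2 passed without the 48 h pair. With robust moderation SERPINB2, DNAJC25-GNG10, RNU86, NDRG1 and S100A8 did not pass, and with no filter 0 genes passed. The count was 811 without the 18 h pair, 1262 without the 36 h pair and 60 with the depth class as a term.

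The last comparison followed both arms together over the 30 h after infection and the switch from 10% to 1% serum; no uninfected library was part of the design. Proliferation genes fell. All 38 G1/S and replication genes fell, over all genes and adjusted over the list alone, with a median log2 change of -1.41 from 18 h to 48 h, among them RFC4 (-1.64, SE 0.12) and CCNE2 (-1.42, SE 0.20). Of 37 G2/M genes 36 fell (37 adjusted over the list alone, median -1.12), MKI67 by 1.73 (SE 0.21) and CDC25C by 1.61 (SE 0.19). Of 16 histone genes 11 fell (12 adjusted over the list alone), including HIST2H4A (-1.48, SE 0.21) and H1F0 (-0.89, SE 0.18). The median fall of G2/M genes came mainly at 48 h: their median level was 0.31 and 0.33 at 18 h, 0.41 and 0.38 at 24 h, 0.12 and 0.09 at 36 h and -0.84 and -0.74 at 48 h in Adeno-GFP and Adeno-DLX3. G1/S genes fell earlier, from 0.58 and 0.57 at 18 h to -0.07 and -0.24 at 36 h. They then fell further, to -0.86 and -0.76 at 48 h. Without the 48 h pair the median slope was -0.0110 log2 per hour for G2/M genes, against -0.0373 with it, and -0.0108 against -0.0287 for histones.

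Interferon, sterol and cell-cell adhesion genes rose over the same time. Of 38 interferon genes 33 rose and 0 fell (34 and 0 adjusted over the list alone, median 1.14), including DDX58 (1.28, SE 0.21), HERC5 (1.25, SE 0.21) and OASL (1.18, SE 0.20). Of 24 cholesterol biosynthesis genes 20 rose and 0 fell (23 and 1 adjusted over the list alone), TM7SF2 by 2.08 (SE 0.25). Of 26 desmosome and cell-cell adhesion genes 18 rose and 1 fell (20 and 1 adjusted over the list alone), DSC2 by 1.09 (SE 0.18) and DSP by 0.67 (SE 0.12). Of 23 unfolded protein response genes 13 rose and 4 fell (14 and 4), of 22 lipid synthesis genes 10 rose (12), of 21 hypoxia genes 9 rose (9) and of 15 terminal differentiation genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), CALML5 up by 0.97 (SE 0.23) and KRT10 at -0.68 (SE 0.15). The rise of hypoxia genes was mainly in 1 arm: their median level went from -0.17 at 18 h to 0.43 at 48 h in Adeno-GFP. In Adeno-DLX3 it went from -0.16 to -0.07. The strongest single rises were those of the complement regulator CFI (2.87, SE 0.33), the TNF family ligand CD70 (2.72, SE 0.23), the collagenase MMP13 (2.61, SE 0.55), caspase 1 (CASP1, 2.42, SE 0.23) and FGFBP1 (2.40, SE 0.13). The strongest falls were those of the cytochrome CYP1A1 (-3.05, SE 0.25), TXNIP (-2.42, SE 0.20), the actin-binding TAGLN (-2.28, SE 0.35), the decoy receptor IL1R2 (-2.17, SE 0.26) and TCF19 (-2.05, SE 0.14). CDKN1A rose by 1.49 (SE 0.19, adjusted p = 0.00104).

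Over the hours 2815 genes passed, 1504 rising and 1311 falling, in a fit that takes the 2 libraries of an hour as independent. On the mean of each pair, with 2 residual degrees of freedom, 1059 passed (584 rising, 475 falling), among them 37 of 38 G1/S, 25 of 37 G2/M, 31 of 38 interferon, 15 of 24 cholesterol, 11 of 26 cell-cell adhesion, 9 of 16 histone, 9 of 23 unfolded protein response (and 2 fallen), 5 of 22 lipid, 4 of 21 hypoxia, 3 of 15 terminal differentiation and 0 of 28 ribosome biogenesis genes, but not DSP, CALML5 or KRT10, and fry passed 0 lists. Camera passed 11 of 34 lists, those above and ribosome biogenesis genes (lower, adjusted p = 0.0213; 4 of 28 fell, 3 adjusted over the list alone; adjusted p = 0.703, with the median turned above 0, without the 18 h pair and 0.133 without the 48 h pair). Terminal differentiation lost its call with no filter (adjusted p = 0.134) and with a filter of RPKM 5 (0.0920), and histones with the latter (0.0509), and the median slope of hypoxia genes was 0.00799 log2 per hour without the 48 h pair, against 0.0148 with it. With an estimated correlation 0 passed (6 had an unadjusted p under 0.05; adjusted p = 0.193 with an estimated correlation for G1/S and for cell-cell adhesion genes, the smallest), and fry passed 15. On the values as deposited, where the median of all genes moved by -0.12 from 18 h to 48 h, 1046 genes rose and 2021 fell. The count was 1064 without the 18 h pair, where MMP13 did not pass, and 261 without the 48 h pair, where CFI did not pass, and with the depth class as a term it was 5186.

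**Figure D5:**
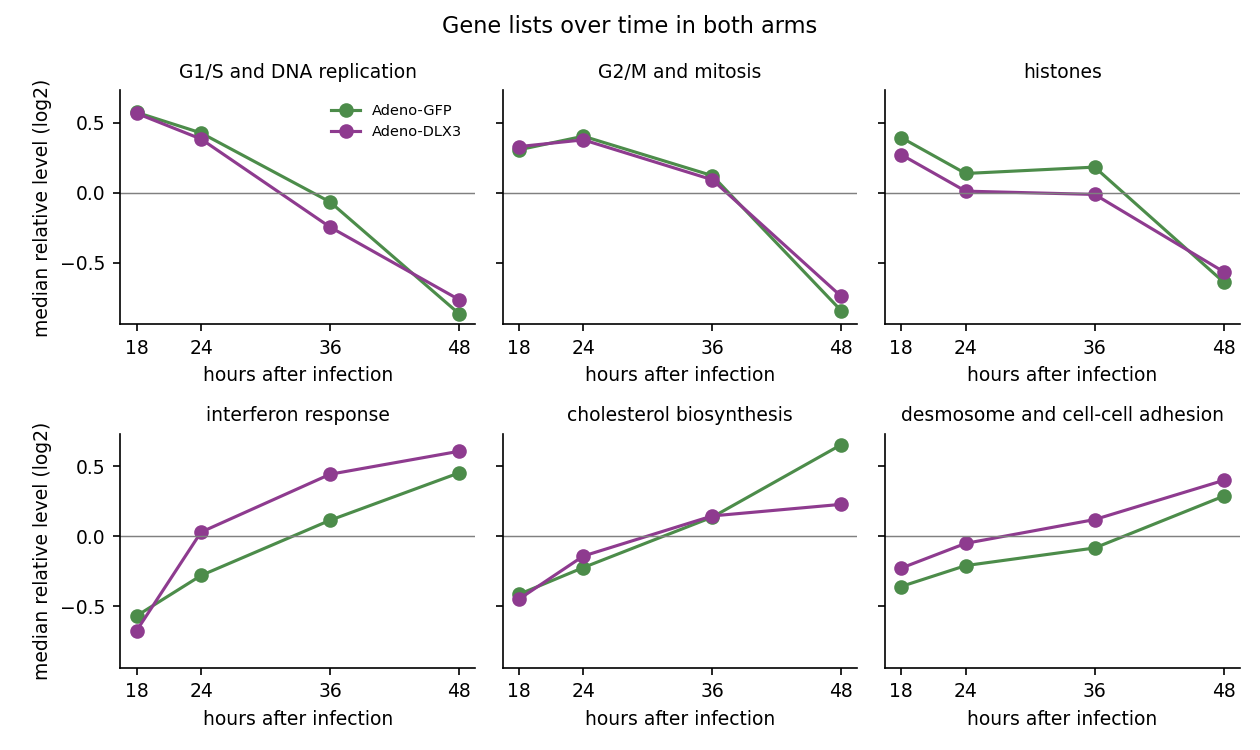
Median level of the genes of 6 lists relative to each gene's mean over the 8 libraries (vertical, log2) against hours after infection (horizontal), with 1 library per point, Adeno-GFP in green and Adeno-DLX3 in purple. G1/S genes went from 0.58 and 0.57 at 18 h to -0.86 and -0.76 at 48 h in Adeno-GFP and Adeno-DLX3.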

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

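The fit with the depth class as a term, the fit on the 18 h and 36 h pairs alone, and the tests of transcript length and GC content for the change of the effect were chosen after the data were seen; the predictions of the other tests were written before.

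Among the named genes that passed for DLX3, 1 of 58 had an hour far from its other 3: KRT16 had a log2 ratio of -0.24 at 48 h. Chance marks about 1 in 20 groups in this way, or 2.9 of 58.

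The effect of DLX3 differed between the hours, by the test of the change itself, for 229 genes. The effect grew from 18 h to 48 h for SERPINB2 (2.69), DNAJC25-GNG10 (2.57), SERPINB7 (2.41), ACHE (2.37), SERPINI1 (2.20), TGM1 (1.98), NID1 (1.95), MSX2 (1.49), F2R (1.29) and ERRFI1 (1.00). It dropped for RNU86 (-2.87), CDH5 (-2.33), NDRG1 (-2.11), S100A8 (-2.11), ZBED6CL (-2.08), S100A9 (-1.99) and PLAT (-1.55).

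The depth classes of the libraries stay open as a source of these changes. If a library class moved the genes, the 24 h libraries, both of lower depth, would lie off the line between 18 h and 36 h on the side opposite to the slope: the median displacement, signed by the slope, was -0.22 log2 over the 229 genes, 170 of them below 0, while the lowest of 10000 random lists had -0.08. Over all 11860 genes the unsigned displacement correlated at -0.570 (Pearson) with the 48 h log2 ratio minus the mean ratio of the other hours. The relation was thus not particular to the 229 genes. With the depth class as a term 60 genes passed, with the same estimates as without the 48 h pair. The log2 ratio also correlated with transcript length at 0.422 at 18 h and -0.0137 at 48 h, and with GC content at -0.145 and 0.403 (Spearman); with the length trend removed from each pair 128 of 230 genes still passed, which leaves length open, and with the GC trend removed 187, which argues against GC content as the whole source. A time course of the DLX3 effect stays open as well.

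HBB and GH1, read in every Adeno-GFP library and at 0 to 3 reads in each Adeno-DLX3 library, were weighed next. Blood or pituitary RNA in the control cultures is argued against, since the highest of HBA1, HBA2, HBD, ALAS2, PRL and POMC was 0.263 RPKM in the Adeno-GFP libraries (HBA2), under the bound of 1.46. Vector pieces in the control virus that carry both sequences stay open. The log2 ratio of HBB to GH1 had an SD of 0.56 over the 4 Adeno-GFP libraries, against 0.54 for HBB and 0.67 for GH1. It lay between the 2, so the test decides neither way. The vector sequence is not given in the sources used here. No biological explanation was tested.

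More genes rose than fell with DLX3, and ribosomal protein genes were lower. On the 11741 genes with both values, 415 passed with no trend removed (282 higher, 133 lower). With the trend in transcript length removed from each pair 366 passed (241 higher, 125 lower). With the trend in GC content removed 782 passed (471 higher, 311 lower), and the share of higher genes was 60.2%, against 68.0% with no trend removed. Both trends are thus argued against as the whole source of the count. The ribosomal protein median was -0.10 after the length trend was removed and -0.13 before, with an SD of 0.07 over the genes, and cell-matrix adhesion, which had passed camera, had an adjusted p of 0.109 after that removal. An effect of DLX3 itself stays open.

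Other groupings of the libraries were counted for the 412 genes. Of 35 splits into 4 and 4, 32 could be fitted with hours, of which 1 (the real one) gave as many genes and the highest other gave 2. The 24 other than the 8 that part all 4 pairs rest on 2 pairs only. Among those 8, 1 gave as many genes and the highest other gave 0, and 8 splits are too few to give a share under 0.05. Over the 12 orders of the pairs, an order and its reverse counted once, 1 (the real one) gave as many as 229 genes with a changing effect and the highest other gave 53, and 12 orders are too few as well.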

How the results depend on the processing

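The fits on the 18 h and 36 h pairs alone, with the depth class as a term, without very short RNA genes and with hours on the mean of each pair were chosen after the data were seen. Over the alternatives, 70 of 102 counts stayed near their value and 32 moved. Of the gene values 1351 kept direction and side of the threshold, 328 lost the threshold, 10 gained it and 8 reversed. Those kept include values of genes that did not pass in the main fit. Of the 58 named genes that passed for DLX3, 43 did not pass without the 24 h pair and 48 without the 36 h pair. Of list tests 262 were kept and 8 lost.

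Genes changed by DLX3 (412) ranged from 42 to 810 over the fits without 1 pair, which have fewer libraries. There were 4 with no filter, 259 with a filter of RPKM 5, where fewer genes were tested, 230 with the transcript of the highest mean, 970 at adjusted p under 0.1 and 15 with the 18 h and 36 h pairs alone. With no replicate block for the pairing by hours there were 25, since the change over hours then adds to the spread. Genes whose effect changes with hours (229) ranged from 58 to 1262 without 1 pair, with 0 under no filter, 26 with the transcript of the highest mean, 113 with hours as ranks and 60 with the depth class as a term. Genes that change with hours (2815) ranged from 261 to 3017 without 1 pair and were 5186 with the depth class as a term and 1059 on the mean of each pair, which leaves 2 residual degrees of freedom. List tests for DLX3 (9) gave 14 with the 18 h and 36 h pairs alone.

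Differences at 18 h (46) were 70 and 25 with pseudocounts of 0.1 and 1, 83 with no filter and 23 with a filter of RPKM 5. At 24 h (106) they were 228 and 39 with these filters, at 36 h (162) 251 and 73, and 244 with a pseudocount of 0.1, and at 48 h (344) 568 and 156.

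Of the 2815 genes 7 turned sign without the 48 h pair and 7 with the transcript of the highest mean; among named genes signs reversed only for some that had not passed. Without 1 pair the log2 fold change ranged from -0.0333 to 0.199 for MLANA, -0.521 to 0.273 for CDH5, -0.0666 to 0.236 for CDKN1A, -0.0332 to 0.115 for MKI67 and -0.0826 to 0.0388 for KRT10. On the 18 h and 36 h pairs alone it was -0.0492 for MLANA, 0.0884 for CDH5 and 0.0426 for TP63. Where no cause is named here, the cause was not tested. Depth limits values under 0.0478 to 0.0866 RPKM, the floor of 3 reads over 1 kb.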

Other observations

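Several genes of the cornified envelope and skin barrier lay under the expression filter, and 15 of the 51 genes of the differentiation list were tested. None of the other 36 was tested: 9 were higher with DLX3 at 4 of 4 hours, 1 was lower at 4 of 4, 8 had 0 RPKM in all libraries and 18 were mixed. The genes named were chosen after their values were seen. Filaggrin (FLG) had a mean of 0.349 RPKM (SD 0.0323) in the Adeno-GFP libraries and 0.845 (SD 0.134) in the Adeno-DLX3 libraries, and was higher with DLX3 at 4 of 4 hours. The same held for the ceramide synthase CERS3 (0.653 and 2.28 RPKM), the transcription factor GRHL3 (0.168 and 0.547) and the envelope protein SPRR1B (0.463 and 0.861), while FLG2 (0.0731 and 0.136) was higher at 3 of 4 and CDSN (0.686 and 0.849) at 2 of 4. The lipoxygenase ALOXE3 (0.825 and 0.587) was lower with DLX3 at 4 of 4 hours. CASP14 had 5.38 RPKM in the Adeno-GFP 48 h library and 1.27 in its Adeno-DLX3 partner. Loricrin (LOR) had 0 RPKM in all 8 libraries, and KRT1 had 0 in 7.

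Genes higher with DLX3 also tended to rise with hours. Of the 281, 112 rose with hours, against 35.6 under independence, and 5 fell, against 31.1. Of the 131 lower genes 17 rose, against 16.6, and 31 fell, against 14.5. Both comparisons share the same 8 libraries; in unchanged simulated libraries of like spread the correlation between the fold change for DLX3 and the change over hours averaged 0.00381, against 0.275 observed; with the change in the Adeno-GFP libraries alone the observed correlation was 0.0845 (simulated -0.0694 to 0.0566). The hypothesis that the rise comes only from a growing DLX3 effect in the Adeno-DLX3 libraries was tested, with its prediction written before. In the Adeno-GFP libraries alone the median change of the 280 higher genes other than DLX3 was 0.29 log2, with 201 above 0. This lay outside the -0.06 to 0.04 that held 5% to 95% of random lists. In these libraries the higher genes thus rose without added DLX3. Random lists carry no spread between libraries, however, each hour has 1 Adeno-GFP library, and that of 48 h was of lower depth. The test therefore cannot decide, and the hypothesis stays open. The 131 lower genes had a median of -0.01 in the Adeno-GFP libraries. This lay inside their own random range of -0.07 to 0.07, which has the same limit.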
